A study of Homo sapiens with 16 samples.

How the data were processed

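The series holds 16 human miRNA arrays, 1 for each of 8 cell lines and 2 treatments (BMP4 at 100 ng per ml or vehicle, 4 hours, per the labels), with 7 breast cancer lines and the mammary epithelial line MCF-10A. The arrays are Agilent 1-colour arrays, and per the file headers their intensity values come from Feature Extraction 10.7.1.1, which subtracted the local background with spatial detrending and applied no normalization between arrays. The series also has a value table of 1410 probes for the same arrays, whose deposited intensity values the authors normalized by a method that neither the labels nor the headers state. Its column medians were 0.21 to 0.28, all 1410 probes were found on the arrays, and its logarithms correlated with the processed signals at r = 0.938 to 0.991 where both exceeded 2; the scale and any centring of that table remain unknown, and it served as an alternative.

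For each array the processed signals of the replicate spots of a probe were averaged, leaving out control spots and the 8.79 to 11.6% of the 14192 other spots with an outlier mark; 0 spots were saturated, and the median coefficient of variation of replicate spots was 21.4 to 38.4%. A probe counted as well above background on an array when at least 50% of its spots did, per the scanner's own call. The 2446 probes measure 887 miRNAs, with 1 to 4 probes each, and each miRNA was read from its brightest probe. Because 41.7 to 54.2% of spots had a processed signal below 0, which has no logarithm, signals were divided by the array's 75th percentile over the 62 probes above background on all arrays, then raised to a common floor of 0.0459 (log2 −4.44; the highest, over the arrays, of the SD of the negative controls divided by the scale factor), and then put on the log2 scale. The floor corresponds to 1.36 intensity units on the dimmest array and 15.2 on the brightest, since the scale factors ran from 29.5 to 332 (11.2-fold). Of the tested values 20.1% lay at the floor, and values there have no order.

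Between 93 and 161 miRNAs were well above background per array. Tests covered the 136 miRNAs whose brightest probe was above background on at least 4 arrays; 751 were not tested, and 39 were above background on all arrays. For levels of single lines, responses that differ between lines and bounds, a miRNA counted as above background by any of its probes (42 on all arrays). Names are those of the array's design, with older entries given by the miRBase release in their suffix (22 such entries on the array, 11 of them tested). Of the tested miRNAs 123 were matched to a hairpin gene symbol in the gene table at hand, and 1 of the 11 older, retired entries. miR-1974 and the other unmatched older entries were thus not established as miRNAs here. No genome build is named in the labels or headers, so no coordinate was used. The older entry miR-1974 alone held 62.8 to 91.5% of the summed signal of an array, and all such entries 74.8 to 93.7%; no array was scaled to its sum.

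Pairing was checked by correlating the arrays of each line as deviations from the mean of the BMP4 or vehicle arrays: the BMP4 array of all 8 lines correlated best with the vehicle array of its own line (r = 0.451 in BT-474, 0.628 in MDA-MB-361 and up to 0.94 elsewhere; highest with another line 0.529). The arrays lay on 2 slides of 8 arrays and 4 lines each, with BT-474, HCC1954, MDA-MB-436 and T-47D on slide 1. In all 8 lines the vehicle array lay in an odd row of the slide and the BMP4 array in an even row, so that row and treatment cannot be told apart.

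Differences were tested on the log2 scale with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. BMP4 was compared with vehicle with the line as a block, in all 8 lines and in the 7 cancer lines. Each line lay wholly on 1 slide, so this block also removes the slide. For this comparison the slide as block in place of the line only drops the pairing of the arrays. MCF-10A, and each other line, was compared with the other 7 lines on the mean of the 2 arrays of a line, and on the BMP4 minus vehicle differences; such a test of 1 line against 7 takes the spread of the 7 as that of the line. Within a line there is 1 array per treatment and no test, so differences of at least 2-fold and at least 1.5-fold were counted. Similarity of responses was the mean Pearson correlation of the differences over the 28 pairs of lines, tested by flipping the sign of whole lines in all 128 distinct ways. The p-values of the comparisons of single miRNAs measure the spread between lines, and their precision is set by the number of lines, while the F test uses the spread between the arrays of a line and camera with its preset correlation largely that between miRNAs: the median SE was log2 0.18 for BMP4 over all lines and 0.64 for MCF-10A against the cancer lines.

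miRNA lists were fixed before the data were examined, as were the comparisons, the filter, the scaling and the alternatives: SMAD-regulated hairpins, miR-302 and miR-367, miR-200, miR-205 and miR-203, let-7, miR-17/92 and paralogs, miR-15/16, miR-34, miR-221 and miR-222, miR-23/27/24, miR-29, miR-30, miR-181, miR-183, miR-96 and miR-182, miR-10, miR-146 and miR-155, hypoxia, the germ line cluster, the chromosome 19 cluster, DLK1-DIO3, markers of mesenchymal, blood, muscle, neural, and endothelial and liver cells, and miRNAs tied to RNA quality or labelling on arrays. Lists with at least 5 tested miRNAs were tested with limma's camera (preset correlation of 0.01), with an estimated correlation, and with fry. Named for BMP4 were the 10 higher and 10 lower miRNAs with the smallest p and up to 3 members of each list; for the cancer lines 5 and 5; for MCF-10A, where fewer than 5 passed, 10 and 10; for a single line the 3 largest in each direction; and for responses that differ the 5 with the smallest p. The F test across lines, the tests within slides for lists and for single lines, the fits without BT-474 and MDA-MB-361 and with brightness as covariate, the responses with each line's median removed, and the summed probe signals were added after the data were seen.

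Alternatives were normexp background correction, the 75th percentile over all probes, quantile normalization, no scaling, no filter, only miRNAs above background on all arrays, the mean over a miRNA's probes, the scanner's gene totals, a higher floor (log2 −3.23), the value table, no block, the slide as block, each slide alone, array weights, trended and robust variances, and leaving out each line in turn. Normexp used the median spot signal with an offset of 50, because the mean spot signal is not among the columns of the files. This offset is large beside the scale factors of 29.5 to 332, so it draws dim miRNAs together. For dim miRNAs a normexp value near that of all tested miRNAs is therefore partly built in. The scanner's gene totals were checked against the probe totals: over the 16 arrays 1759 of 2427 detected totals equalled the sum of the miRNA's own detected probes (signal above 3 times its error) within 0.1% plus 0.01, and the remaining 668 (30 to 60 per array) also held the total of the preceding entry, with 0 unexplained. The main values do not use these totals, and a sum of detected probes without that carry-over was added beside them.

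The steps were tested on simulated data with the real levels and spread of the 136 tested miRNAs and normal noise. For BMP4 over all lines 44%, 90.5% and 99.5% of changes of log2 0.5, 1 and 2 were recovered; for 1 line against 7 it was 1%, 57.5% and 95.5% of differences of log2 1, 2 and 4. Runs for single miRNAs changed 10 miRNAs per size of change. No floor was set in the simulated data, and the noise of a miRNA had the same size in all lines. A list of 20 shifted by 0.3 was called by camera (p under 0.05) in 100% of runs and an unshifted list in 0%. The noise was independent between miRNAs, so these list rates do not hold for lists with correlated members. In the real arrays the estimated correlation was 0.351 for the list tied to RNA quality and 0.956 for miR-23/27/24. Of the calls for single miRNAs 3.9% were false, and 20 runs without any change gave 3 calls.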

Results

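MicroRNAs were measured in 7 human breast cancer cell lines (BT-474, HCC1954, MCF-7, MDA-MB-231, MDA-MB-361, MDA-MB-436 and T-47D) and in the mammary epithelial line MCF-10A, each kept for 4 hours with BMP4 at 100 ng per ml or with vehicle. BMP4 is a ligand of the TGF-beta superfamily that signals through receptor SMAD proteins, which act on transcription and also on the processing of some miRNA hairpins. Each line and treatment was measured on 1 array, so the 8 lines are the replicates and the spread between cultures of a line is unknown. Of the 887 human miRNAs on the array, 136 were well above background on at least 4 of the 16 arrays and were tested, and 546 were above background on none. Among the tested were 11 older, retired entries, named below by their miRBase release. Only 1 of these matched a hairpin gene symbol, so the others were not established as miRNAs. The cluster of miR-302 and miR-367, which is active in pluripotent cells and has been described as a BMP target, had 0 of its 10 miRNAs among those tested. The HIF target miR-210 and the NF-kB responsive miR-146 and miR-155 were likewise not among them.

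After BMP4 the 3 measured members of the miR-29 family, which represses collagens and other matrix genes, averaged above vehicle over the 8 lines: miR-29b-3p by log2 0.51 ± 0.20 (SE; 1.43-fold), miR-29a-3p by 0.42 ± 0.17 (1.34-fold) and miR-29c-3p by 0.36 ± 0.14 (1.28-fold). The median difference of all tested miRNAs was −0.04, and some settings moved it as a whole: to 0.63 with scaling over all probes, 0.38 without scaling, 0.19 in the series' value table, −0.13 with the scanner's gene totals and −0.21 with normexp background correction. Relative to that median the miR-29 family's median was 0.46, and between 0.08 (normexp) and 0.77 (quantile normalization) in the other settings. Normexp adds an offset of 50 intensity units to every signal, which draws dim miRNAs together. Small relative values with normexp, here and below, are partly built in for such miRNAs. The miRNAs of the clustered miR-23, miR-27 and miR-24 genes also averaged above vehicle (median 0.47; relative to all 0.51, and 0.22 with normexp). They were led by miR-27a-3p (0.52 ± 0.22, 1.43-fold), miR-23a-3p (0.52 ± 0.24, 1.44-fold) and miR-27b-3p (0.47 ± 0.24), each above vehicle in 7 of 8 lines; without BT-474 they were at 0.32, 0.27 and 0.23. Next came miR-141-3p of the epithelial miR-200 family (0.58 ± 0.25; 0.34 without BT-474), miR-21-3p (0.32 ± 0.14) and miR-21-5p (0.40 ± 0.19; 0.26 without BT-474) from a hairpin whose processing SMADs are known to promote. miR-16-5p, a brake on the cell cycle, averaged 0.50 ± 0.29, and 0.19 without BT-474, where it was at 2.70. Relative to all tested miRNAs, miR-141-3p was at 0.16, miR-16-5p at 0.15 and miR-21-3p at 0.00 with normexp. miR-16-5p and miR-29a-3p turned to −0.28 and −0.01 with the gene totals, and miR-21-3p to −0.02 in the value table. Neither turn under the gene totals recurred with summed probe signals. On the other side, miR-513a-5p averaged −0.68 ± 0.21, with values below vehicle in all 7 cancer lines and 0.61 above it in MCF-10A.

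None of these differences passed the test. In limma 0 of 136 miRNAs reached an adjusted p of 0.05 (smallest adjusted p = 0.321). An unadjusted p under 0.05 was found for 19, 6 of them higher and 13 lower, where 6.8 would be expected by chance. A single other setting changed that count: scaling each array to the 75th percentile over all probes called 44 miRNAs, all higher, with 63 unadjusted. That setting also raised the median difference of all tested miRNAs to 0.63 from −0.04. Its divisors ran only from 0.602 intensity units (HCC1954, BMP4) to 2.46 (MDA-MB-231, vehicle), where the SD of the negative controls was 1.44 and 2.92. It thus divides by signals about as large as the background noise. All other settings and tools called 0, with between 1 (normexp) and 25 (the series' value table) unadjusted. With the slide as block in place of the line 0 were called and 3 had an unadjusted p under 0.05. That fit drops the pairing of the arrays, and the line block already removes the slide, so the lower count is not an adjustment for slide. Within slide 1 and slide 2 the counts were 0 and 0, with 4 and 4 unadjusted. On simulated arrays of this design the same test recovered 44% of changes of log2 0.5 and 90.5% of changes of log2 1. Each run changed 10 miRNAs at each of log2 0.5, 1 and 2, and many true changes ease the adjusted threshold. Recovery of a few small changes alone was not simulated. No floor was set in the simulation, and every line received the same change with noise of the same size. In the real arrays 20.1% of tested values lay at the floor, so recovery there may be lower.

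**Figure D1:**
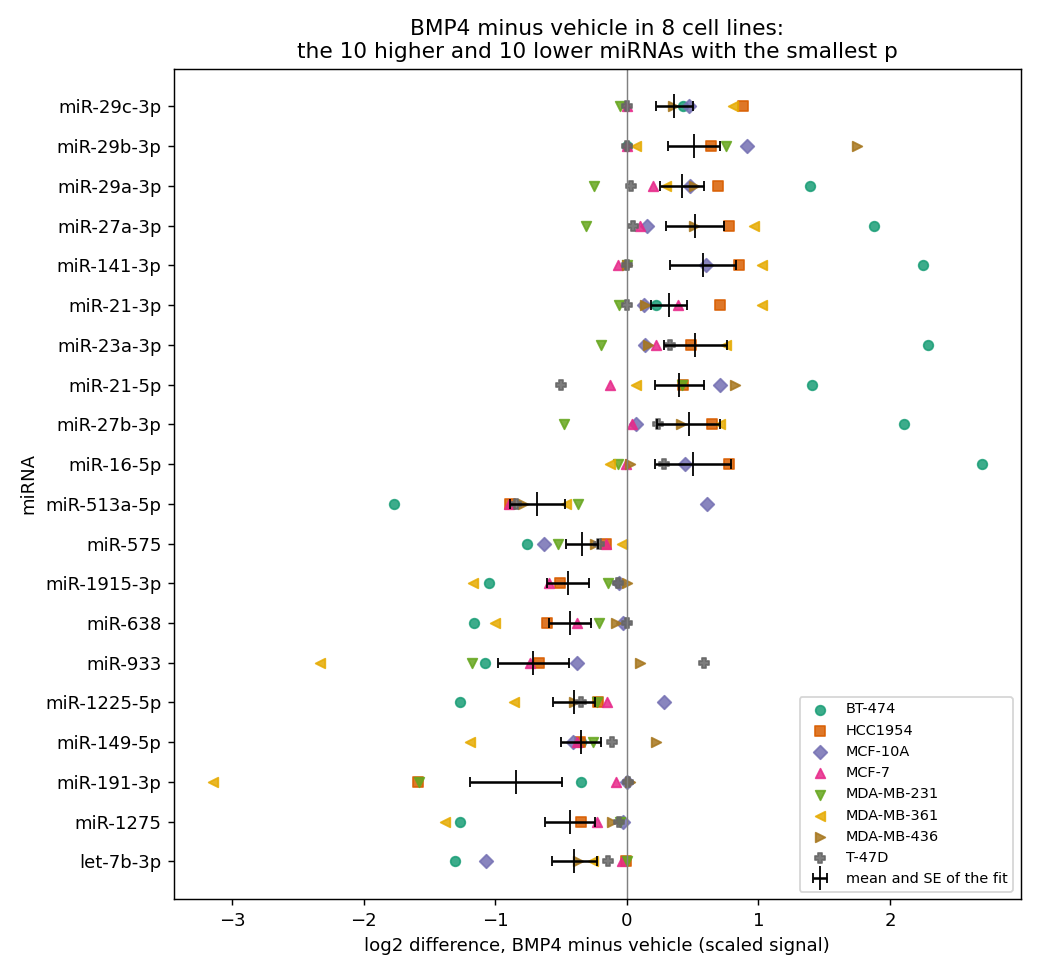
BMP4 minus vehicle (log2, horizontal axis) in each of the 8 lines (points) with the mean and its SE (black bars) for the 10 higher and 10 lower miRNAs with the smallest p (vertical axis); the highest mean is miR-141-3p at log2 0.58 ± 0.25 and the lowest miR-191-3p at −0.84 ± 0.35. Relative to the median of all tested miRNAs, the median of the miR-29 family lies at 0.46 here and at 0.08 with normexp, and that of the miRNAs tied to RNA quality at −0.29 here, −0.22 with scaling over all probes and −0.27 without scaling.

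Among the lower miRNAs with the smallest p, 5 came from a list of purine-rich or GC-rich species whose array signal is often tied to RNA quality or labelling. Of these, miR-1915-3p (−0.45 ± 0.16), miR-638 (−0.43 ± 0.16), miR-1275 (−0.43 ± 0.19) and miR-575 (−0.34 ± 0.12) were at or below vehicle in 8 of 8 lines. miR-1225-5p (−0.40 ± 0.16) was in 7. Relative to all tested miRNAs miR-1275 turned to 0.16 with the gene totals. The remaining 5 were miR-513a-5p, miR-191-3p (−0.84 ± 0.35, with 5 lines below vehicle and MDA-MB-361 at −3.15; −0.51 without that line) and miR-933 (−0.71 ± 0.27, 6 lines below), together with let-7b-3p (−0.40 ± 0.17, 7 lines below) and miR-149-5p (−0.35 ± 0.15, 7 lines below). Several of these were near the limit of the array: miR-29b-3p was well above background on 8 of the 16 arrays, miR-141-3p on 7, let-7b-3p on 8, miR-29a-3p and miR-29c-3p on 10, and miR-513a-5p on 12. By contrast miR-27a-3p, miR-23a-3p, miR-21-5p, miR-638 and miR-149-5p were on all 16.

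Taken as groups, 20 of 20 measured miRNAs of the RNA-quality list were lower after BMP4 (median log2 −0.33). Relative to all tested miRNAs the list's median was −0.29, and between −0.37 and −0.07 (normexp) in the other settings. Against 0 the list's median was 0.11 without scaling and 0.41 with scaling over all probes, so its fall is one relative to other miRNAs. The list fell in camera (adjusted p = 4.48e-05), but not with an estimated correlation (adjusted p = 0.278) or in fry (adjusted p = 0.132). All 5 measured miRNAs of the miR-23/27/24 clusters were higher (median 0.47; relative to all 0.51, and 0.22 to 0.63 in the other settings), and camera called the list higher (adjusted p = 0.00107). The list's mean was 0.43, and 0.20 without BT-474. The call was lost with an estimated correlation (adjusted p = 0.278) and in fry (adjusted p = 0.277). Adjusted over the list alone, 0 miRNAs of either list passed, and 7 of the quality list and 1 of the clusters had an unadjusted p under 0.05. All 3 measured miR-29 members passed when adjusted over their list alone (largest adjusted p = 0.0317), as 0 members of the other lists did. These adjustments were not corrected for the number of lists, and over all tested miRNAs the limma adjusted p was 0.321 for each. The difference of miR-29b-3p was 0 in BT-474, MCF-7 and T-47D, and that of miR-29c-3p in MCF-7 and T-47D. With normexp the family's median was only 0.08 above that of all. In the same arrays the RNA-quality list was lower. Its mean was −0.90 in BT-474, −0.24 in HCC1954, −0.11 in MCF-10A, −0.31 in MCF-7, −0.19 in MDA-MB-231, −0.74 in MDA-MB-361, −0.04 in MDA-MB-436 and 0.00 in T-47D.

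With the slide as block in place of the line, a fit without the pairing, camera gave adjusted p of 0.000473 for the miR-23/27/24 clusters and 0.000178 for the quality list. These and the values within slides use the preset correlation, and with an estimated one both lists lost their call with the line as block (adjusted p = 0.278 for each). Within slide 1 the medians were 0.80 for the miR-23/27/24 clusters (camera adjusted p = 0.00724) and −0.25 for the quality list (2.35e-05), and within slide 2 they were 0.08 (0.0377) and −0.30 (0.0609). By line, the miR-23/27/24 median was 2.06 in BT-474, 0.71 in MDA-MB-361, 0.49 in HCC1954, 0.24 in T-47D, 0.17 in MDA-MB-436, 0.07 in MCF-7 and in MCF-10A, and −0.31 in MDA-MB-231. Without BT-474 and MDA-MB-361 it was 0.15 and no longer passed (adjusted p = 0.0619), and the quality list's was −0.15 (adjusted p = 0.000319). The miR-29 median ran from −0.05 in MDA-MB-231 to 0.69 in HCC1954.

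**Figure D2:**
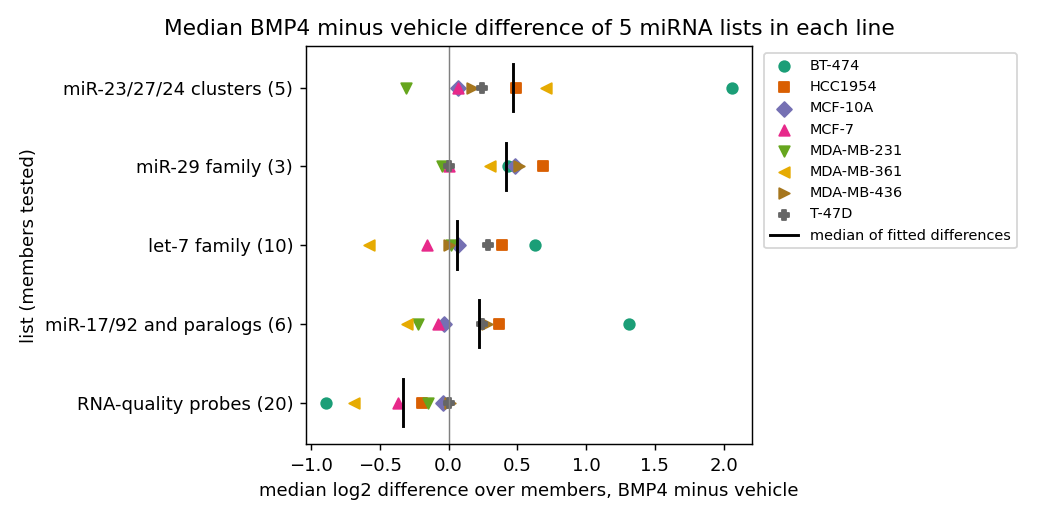
Median BMP4 minus vehicle difference (log2, horizontal axis) in each line (points) and of the fitted differences (black bars) for 5 miRNA lists: 0.47 for miR-23/27/24, 0.42 for miR-29, 0.22 for miR-17/92, 0.06 for let-7 and −0.33 for the RNA-quality list. Relative to the median of all tested miRNAs these are 0.51, 0.46, 0.26, 0.10 and −0.29, and with normexp 0.22, 0.08, 0.03, 0.10 and −0.07. The quality list lies at −0.22 with scaling over all probes and −0.27 without scaling, and miR-17/92 at 0.00 among miRNAs above background on all arrays.

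The other lists held fewer or less even shifts. In the miR-17/92 cluster and its paralogs, which promote proliferation, 5 of 6 measured members were higher (median 0.22; relative to all 0.26, but 0.03 with normexp and 0.00 among miRNAs above background on all arrays). They were led by miR-20a-5p (0.41 ± 0.24) and miR-25-3p (0.38 ± 0.26). In BT-474 these were at 2.01 and 2.26, against means of 0.18 and 0.11 in the other 7 lines. Without BT-474 the list's median was 0.05 and its mean 0.05. The list did not pass in camera (adjusted p = 0.0729, 0.405 with an estimated correlation). In the differentiation-linked let-7 family 7 of 10 were counted as higher, though let-7b-5p and let-7e-5p among them lay at 0.00. The family's median was 0.06 (relative to all 0.10, and 0.02 to 0.22 in the other settings). It did not pass in camera (adjusted p = 0.321, 0.634 with an estimated correlation). Its members with the smallest p were let-7b-3p, let-7f-5p (0.27 ± 0.18) and let-7f-1-3p (−0.38 ± 0.26). With the slide as block, a fit without the pairing, miR-17/92 passed in camera (adjusted p = 0.0348) and let-7 did not (0.205). The sign of these 2 lists differed between slides, with medians of 0.52 and 0.38 in slide 1 (adjusted p = 0.0101 and 0.0262) and −0.11 and −0.20 in slide 2 (adjusted p = 0.302 and 0.265). In the miR-200 family, which restrains ZEB1 and ZEB2, 4 of 4 were higher (median 0.26; relative to all 0.30, and 0.06 to 0.60 in the other settings), and 0 passed over the list alone. After miR-141-3p came miR-200a-3p (0.29 ± 0.19) and miR-200b-3p (0.23 ± 0.23). In BT-474 miR-200a-3p was at 1.55 and miR-200b-3p at 1.91, against means of 0.11 and −0.01 in the other 7 lines. Of the hairpins described as SMAD-regulated, miR-21-3p, miR-21-5p and miR-23b-3p (0.30 ± 0.21) were measured, 3 of 3 higher. For miR-23b-3p BT-474 was at 1.82, and the other 7 lines averaged 0.09. The list's median was 0.32 (relative to all 0.36, and 0.28 to 0.46 in the other settings). Over the list alone 0 passed (smallest adjusted p = 0.0959).

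Lists with fewer than 5 measured members were described without a set test. For miR-15/16 (miR-16-5p and miR-15b-5p, 2 of 2 higher) the median relative to all was 0.30. It was −0.14 with the gene totals, but 0.32 with summed probe signals, free of the carry-over in those totals. The medians were 0.26 for miR-15/16 and 0.13 for miR-30 (4 of 4 higher, relative to all 0.17, and 0.01 to 0.68 in the other settings). They were 0.17 for miR-34a-5p, a p53 target (relative to all 0.21, but −0.40 in the value table), and −0.12 for miR-181 (2 of 2 lower; relative to all −0.07, but 0.07 with normexp and 0.01 without scaling). For miR-221 and miR-222 the median was −0.05 (2 of 2 lower; relative to all −0.01, but 0.01 with the gene totals and 0.08 in the value table). Adjusted over the list alone, 0 members of any of them passed. The epithelial miR-205-5p was at 0.08 ± 0.09, miR-371a-5p of the germ line cluster at 0.06 ± 0.21, and the imprinted DLK1-DIO3 cluster (1 of 3 higher) at a median of −0.04. Markers of other cell types gave 0.13 for the mesenchymal miR-125b-5p and miR-100-5p (2 of 2 higher; relative to all 0.17, and 0.05 to 0.37 in the other settings) and −0.09 for miR-150-3p of blood cells (relative to all −0.04, but 0.07 with the gene totals). The lists for miR-183, miR-96 and miR-182, miR-10, the chromosome 19 cluster, muscle, neural, and endothelial and liver cells had 0 tested members.

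In the 7 cancer lines alone, miR-513a-5p was lower after BMP4 in 7 of 7 lines (mean log2 −0.86 ± 0.17, SE; well above background on 12 of the 16 arrays), and its adjusted p was 0.0969. Below vehicle in 6 or 7 lines were also miR-574-5p (−0.57 ± 0.19), miR-1225-5p (−0.50 ± 0.16), miR-1915-3p (−0.50 ± 0.17) and miR-638 (−0.49 ± 0.17), the last 3 of the RNA-quality list. The higher miRNAs with the smallest p were miR-27a-3p (0.57 ± 0.25), miR-23a-3p (0.58 ± 0.27), miR-29a-3p (0.41 ± 0.19), miR-29c-3p (0.34 ± 0.15) and miR-21-3p (0.35 ± 0.15). Without BT-474 the first 3 were at 0.35, 0.29 and 0.24, and without MDA-MB-361 miR-21-3p was at 0.23. The median of all tested miRNAs was −0.05 in these lines, −0.18 with normexp and 0.57 with scaling over all probes. Relative to it the last 3 were at −0.02, −0.03 and 0.01 with normexp, and miR-574-5p, miR-1225-5p, miR-1915-3p and miR-638 at −0.40, −0.33, −0.33 and −0.32 with scaling over all probes. miR-29a-3p also turned with the gene totals (−0.09), and miR-21-3p in the value table (−0.08). In limma 0 of 136 passed, with 16 unadjusted (3 higher, 13 lower). miR-513a-5p passed with array weights (−0.78, adjusted p = 0.00733) and without BT-474 (−0.71, adjusted p = 0.0378), and averaged −1.07 within slide 1 and −0.58 within slide 2. All other settings called 0, with 1 (normexp) to 46 (scaling over all probes) unadjusted. There were 4 unadjusted with the slide as block, which drops the pairing, and 4 and 2 within slides 1 and 2.

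In these lines 19 of 20 miRNAs of the RNA-quality list were lower (median −0.37; camera adjusted p = 2.84e-05, 0.27 with an estimated correlation, 0.166 in fry). In the miR-23/27/24 clusters 5 of 5 were higher (median 0.52; adjusted p = 0.000696, 0.27 with an estimated correlation). The miR-17/92 list passed in camera (5 of 6 higher, median 0.25, adjusted p = 0.049) but not with an estimated correlation (adjusted p = 0.352). let-7 had 5 of 10 higher (median 0.07, adjusted p = 0.33). The 3 miR-29 members were higher (median 0.41), and 0 passed over the list alone. With the slide as block, again without the pairing, the camera adjusted p were 0.000248 for the quality list, 0.000392 for miR-23/27/24, 0.0198 for miR-17/92 and 0.189 for let-7. Within slide 1 the lines are the same as above. Within slide 2 the medians were −0.37 (0.0799), 0.10 (0.0103), −0.14 (0.309) and −0.27 (0.116).

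In BT-474, 24 miRNAs had a larger and 1 a smaller BMP4 response than in the other 7 lines (25 in limma, adjusted p under 0.05). These included let-7g-5p (2.53 ± 0.35 above the other lines' mean response, SE), miR-16-5p (2.52 ± 0.36), miR-30b-5p (2.0 ± 0.30), miR-200b-3p (1.92 ± 0.30) and miR-106b-5p (1.83 ± 0.25). The adjusted p was 0.00333 for miR-200b-3p and 0.00279 for the others. Limma's array weights were lowest for BT-474 (0.216) and MDA-MB-361 (0.28), against 1.29 to 1.92 for the other lines. All 5 were well above background on the BMP4 array of BT-474 and not on its vehicle array, so the difference between the arrays is a bound: at least 5.65-fold, 5.71-fold, 3.5-fold, 3.75-fold and 3.1-fold. Such a bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest signal among probes well above background and the dim probe's own. Of the 24 miRNAs 12 were above background on both arrays, among them miR-23a-3p (2.29 in BT-474), miR-27b-3p (2.11) and miR-26a-5p (2.09). The lower one was miR-563 (−1.69 against the other lines).

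Responses of MDA-MB-361 and BT-474 correlated at r = 0.389 over the 39 miRNAs above background on all arrays. In MDA-MB-361, however, the called miRNAs were mostly lower, with 14 lower and 1 higher than in the other lines (15 in all). The 5 with the smallest p were miR-1825 (−3.14 ± 0.35, adjusted p = 0.00101), miR-425-3p (−2.85 ± 0.38), miR-1234-3p (−2.82 ± 0.50), miR-940 (−2.68 ± 0.41) and miR-1238-3p (−2.44 ± 0.48, adjusted p = 0.0156). The scaled difference between the arrays was at least 9.26-fold for miR-1825, 7.92-fold for miR-425-3p and 9.3-fold for miR-1234-3p, which were not well above background on the BMP4 array. Before scaling the same bounds were 1.46-fold, 1.25-fold and 1.47-fold. Of the 14, 10 were measured on both arrays by any probe (9 by the brightest probe) and 3 belong to the RNA-quality list. The vehicle array of MDA-MB-361 was the dimmest, with a scale factor of 29.5 against 187 for its BMP4 array, and the factors were 82.7 and 154 for the vehicle and BMP4 arrays of BT-474.

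For BT-474 the split of higher and lower was 22 and 6 with quantile normalization, 10 and 12 with the gene totals, 15 and 22 with summed probe signals and 2 and 0 in the value table. With the gene totals let-7g-5p turned to −0.06 and miR-200b-3p to −4.03 (adjusted p = 0.000101); with summed probe signals they were at 2.11 and 1.99 (adjusted p = 0.000638). With scaling over all probes, without scaling and with normexp 0 were called (6, 11 and 0 unadjusted). In the first 2 of these settings 24 of the 24 miRNAs stayed above 0, with a median response of 2.35 and 2.82 against 1.89. Their median difference from the other lines was 1.47 and 2.36, against 1.83, while the median SE grew to 0.97 and 1.06 from 0.34, which ended the calls. With normexp, whose offset draws dim miRNAs together, the difference itself fell to 0.32 (median SE 0.66). These settings shift all miRNAs of a line, so each line's median response was also removed, in a test chosen after the data were seen. Of the 24 miRNAs, 24 were then called higher with the original scaling, 22 with scaling over all probes, 22 without scaling, 21 with quantile normalization and 1 with normexp, where the median difference from the other lines was 0.60 (median SE 0.21).

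For MDA-MB-361 the splits were 13 and 1 with scaling over all probes, 29 and 1 without scaling, 0 and 47 with normexp, and 9 and 6 with quantile normalization. These followed the median of all tested miRNAs in this line, which was 1.96, 2.05, −1.23 and 0.34 in these settings and −0.23 in the original scaling. Relative to that median the 14 miRNAs lay at −1.49, −1.46, −0.25 and −1.54, against −1.84. With the line medians removed 4, 6, 0 and 7 of the 14 were called lower, against 9 with the original scaling. The split was 5 and 15 with the gene totals, 2 and 2 with summed probe signals, and 10 and 2 in the value table. With the slide as block the splits were 18 and 0 for BT-474 and 0 and 4 for MDA-MB-361, and within the line's own slide 16 and 3, and 2 and 18.

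In MCF-10A, the line of non-malignant origin, 0 miRNAs responded differently from the cancer lines in limma (smallest adjusted p = 0.986, 4 unadjusted). Its largest differences were 1.0 for miR-1308 as named in release 15, 0.91 for miR-29b-3p and 0.91 for miR-494, and −1.07 for let-7b-3p, −1.07 for miR-1234-3p and −0.88 for miR-1238-3p. Other settings called 13 without a filter, 3 with the higher floor and 2 with summed probe signals; without a filter or with the higher floor, miRNAs at the floor in all other lines have no variance. All others called 0 (0 to 11 unadjusted), including the slide as block (3 unadjusted) and the line's own slide (4). On simulated arrays without a floor, this test of 1 line against 7 recovered 1% of differences of log2 1 and 57.5% of log2 2. HCC1954, MCF-7, MDA-MB-231, MDA-MB-436 and T-47D likewise had 0 called, with 3, 1, 1, 4 and 1 unadjusted.

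Within single lines, differences of at least 2-fold among miRNAs above background on both arrays were few outside BT-474 (12 higher and 19 lower of 87) and MDA-MB-361 (3 and 19 of 66). HCC1954 had 0 and 1 of 74 (largest miR-29c-3p 0.88, miR-22-3p 0.87 and miR-27a-3p 0.78; miR-191-3p −1.59). MDA-MB-231 had 0 and 2 of 91. Its largest were miR-29b-3p (0.75), miR-720 as named in release 18 (0.52) and miR-21-5p (0.42). Its lowest were miR-191-3p (−1.58), miR-33b-3p (−1.02) and miR-1975 as named in release 15 (−0.79). MDA-MB-436 had 1 and 0 of 76 (miR-1274b as named in release 16 at 1.08, miR-1260a 0.87; miR-494 −0.91). MCF-10A had 1 and 2 of 105, MCF-7 0 and 0 of 103 (miR-33b-3p 0.57, miR-21-3p 0.39; miR-1290 −0.98, miR-135a-3p −0.92, miR-513a-5p −0.90). T-47D had 0 and 0 of 87. Its largest were let-7f-1-3p (0.91), miR-33b-3p (0.87) and let-7a-5p (0.52). Its lowest were miR-138-2-3p (−0.74), miR-1308 as named in release 15 (−0.65) and miR-21-5p (−0.50). In BT-474 the lowest were miR-563 (−1.96), miR-1973 (−1.82) and miR-1268a (−1.55). In MDA-MB-361 they were miR-940 (−2.87), miR-1238-3p (−2.68) and miR-1228-3p (−2.07). The highest in MDA-MB-361 were miR-1975 (1.19) and miR-1308 (1.12), both as named in release 15, and miR-141-3p (1.03).

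Over the 39 miRNAs above background on all arrays, the responses of any 2 lines correlated at a mean Pearson r of 0.109. Of the 28 pairs 18 were above 0, and r ran from −0.634 for MCF-10A and T-47D to 0.697 for BT-474 and HCC1954. The mean exceeded that of most sign flips of the lines (one-sided exact p = 0.0391, all flips, highest other mean 0.158). It was 0.073 with quantile normalization (exact p = 0.102), 0.00467 with normexp (exact p = 0.375) and 0.0361 without BT-474 and MDA-MB-361 (exact p = 0.312).

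MCF-10A and the 7 cancer lines differed most in miR-205-5p, a basal epithelial miRNA, whose mean level was log2 5.24 ± 2.93 higher in MCF-10A (3.55) than in the cancer lines (−1.69, SD 3.48). In the cancer lines it ran from the floor to 3.40 and was well above background on 7 of 14 arrays. Also higher in MCF-10A on average were miR-125b-5p (2.67 ± 1.56), miR-29b-3p (1.66 ± 1.1), the p53 target miR-34a-5p (1.37 ± 0.77), and miR-22-3p (1.35 ± 0.84). With smaller differences came miR-24-3p (0.93 ± 0.62), let-7a-5p (0.74 ± 0.46), miR-1288 (0.82), miR-1181 (0.91) and miR-1308 as named in release 15 (1.19). Lower were miR-149-5p (−1.43 ± 0.90), miR-33b-3p (−1.16 ± 0.58), miR-191-3p (−1.11), and miR-25-3p (−1.1 ± 0.49) and miR-93-5p (−0.84 ± 0.57) of the miR-17/92 paralogs. So were miR-574-5p (−1.07), miR-1280 as named in release 18 (−1.02), miR-92b-3p (−0.98), miR-1281 (−0.93) and miR-1260a (−0.83). The median difference of all tested miRNAs was −0.21 here, 0.99 without scaling, 0.27 with scaling over all probes, 0.21 in the value table and −0.69 with normexp. Relative to it miR-29b-3p and miR-34a-5p were at 0.46 and 0.44 with normexp, against 1.87 and 1.58. miR-1260a turned to 0.27 with normexp, and miR-92b-3p to 0.56 with the gene totals. In limma 0 of 136 passed (smallest adjusted p = 0.88, 1 unadjusted). Without a filter 11 were called higher, again on floor values without variance, and 0 in all other settings (0 to 36 unadjusted; 1 and 1 with the slide as block and within the slide of MCF-10A).

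The let-7 family was higher in MCF-10A (7 of 10, median 0.75, mean 0.46; median relative to all 0.96, and 0.35 with normexp) and passed in camera (adjusted p = 0.0301). It did not pass with an estimated correlation (adjusted p = 0.125) or in fry (adjusted p = 0.428). With the slide as block its median was 0.24 (adjusted p = 0.0451), and within the slide of MCF-10A 0.24 (adjusted p = 0.0579). The miR-23/27/24 clusters had a median of 0.73 (3 of 5 higher, camera adjusted p = 0.277). The miR-17/92 median was −0.06 (3 of 6 higher, camera adjusted p = 0.626), but 0.15 relative to all, and −0.08 to 0.20 in the other settings. That of the RNA-quality list was −0.29 (14 of 20 lower, camera adjusted p = 0.626). Relative to all it was −0.08, but 0.10 among miRNAs above background on all arrays. Among smaller lists the medians were 2.16 for miR-221 and miR-222 (relative to all 2.37, and 1.1 with normexp), 2.02 for the mesenchymal list (relative to all 2.22, and 0.78 with normexp), and 1.66 for miR-29 (relative to all 1.87, and 0.50 with normexp). They were −0.39 for miR-200 (1 of 4 higher, relative to all −0.18, and −0.84 to −0.07 in the other settings) and −0.43 for miR-30 (0 of 4 higher). Relative to all miR-30 was at −0.22, but at 1.29 with the gene totals. With summed probe signals, free of the carry-over in those totals, it was at −0.30. For miR-15/16 the median was −0.50 (relative to all −0.29, and −0.78 to −0.02 in the other settings). For the SMAD-regulated hairpins it was −0.53 (relative to all −0.33, but 0.06 with quantile normalization, 0.13 in the value table and 0.03 with normexp). Over the list alone 0 members of these lists passed.

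The lines themselves differed widely, in markers chosen here after their values were seen. The epithelial miR-200c-3p, which holds down ZEB1, was above background on both arrays of MDA-MB-361 (1.29 ± 0.11, where ± is the distance of each array from their mean), BT-474 (0.59), HCC1954 (0.36), MCF-7 (−0.02), MCF-10A (−0.46) and T-47D (−0.52). It was so on no array of MDA-MB-231 or MDA-MB-436. miR-221-3p, which targets the cell cycle inhibitor CDKN1B, was above background in MDA-MB-231 (0.52 ± 0.18), HCC1954 (−0.16), MCF-10A (−0.53) and MDA-MB-436 (−1.22) alone, and its neighbour miR-222-3p in the same 4 lines. miR-205-5p was measured at 3.55 ± 0.10 in MCF-10A, 3.40 ± 0.06 in HCC1954, 1.96 ± 0.05 in MDA-MB-361 and 0.38 ± 0.07 in T-47D, on 1 array of BT-474 and on none of the other 3 lines. Across the 8 lines 88 of 136 miRNAs differed in limma's F test, which was added after the data were seen (adjusted p = 2.86e-11 for miR-205-5p and 6.5e-09 for miR-221-3p). Within slide 1 the count was 51 and within slide 2 it was 76.

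**Figure D3:**
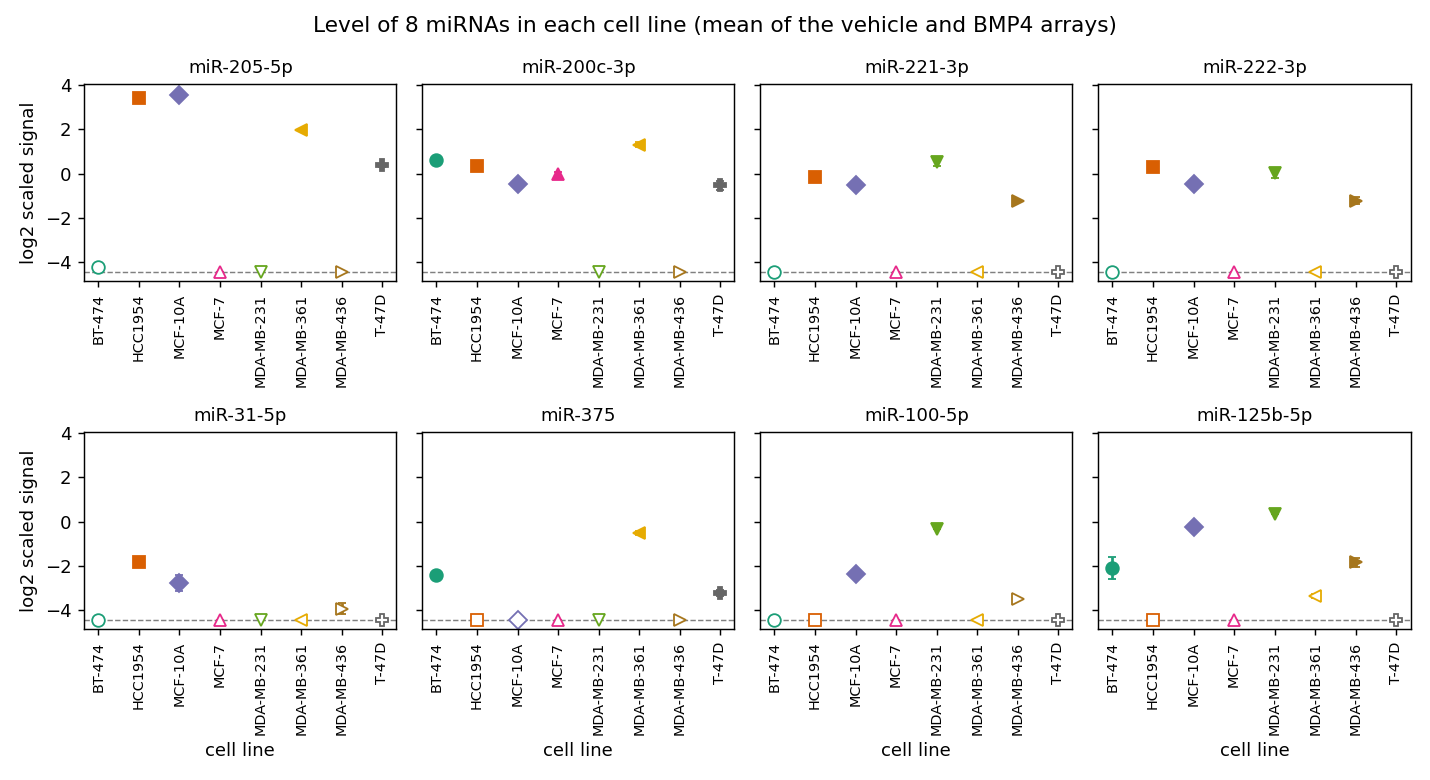
Levels (log2 scaled intensity, vertical axes) of 8 miRNAs in each line (horizontal axes), as the mean of the vehicle and BMP4 arrays with bars reaching each array, open symbols where not above background on both arrays, and a dashed line at the floor of log2 −4.44. miR-200c-3p is above background on both arrays of 6 lines (highest MDA-MB-361, 1.29) and miR-221-3p on those of MDA-MB-231, HCC1954, MCF-10A and MDA-MB-436, while miR-375 is above it in BT-474, MDA-MB-361 and T-47D.

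Set against the mean of the other 7 lines, MDA-MB-231 had 3 higher miRNAs, miR-100-5p (3.69 ± 0.78), miR-30a-5p (2.84 ± 0.59) and miR-99a-5p (2.19 ± 0.43; adjusted p = 0.0348 for each). T-47D had 2, miR-615-3p (2.66 ± 0.53) and miR-196a-5p (2.40 ± 0.49; adjusted p = 0.0384), both of which lie in HOX gene clusters. The other lines were well above background on 5 of 14 arrays for miR-30a-5p and on 2 of 14 for the remaining 4, with means of −4.31 to −4.01 near the floor of log2 −4.44, so these differences depend on the floor. As bounds they were at least 11.5-fold, 6.73-fold and 3.96-fold in MDA-MB-231 and at least 5.86-fold and 4.99-fold in T-47D. In both lines 0 were called with quantile normalization, with the slide as block (11 and 9 unadjusted) and within the line's own slide (8 and 9 unadjusted). The other 6 lines had 0 called, with 4 unadjusted in BT-474, 2 in HCC1954, 1 in MCF-10A, 15 in MCF-7, 6 in MDA-MB-361 and 8 in MDA-MB-436. Within its own slide MDA-MB-361 had 1 called higher (14 unadjusted), and 0 were called elsewhere with the slide as block or within it.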

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

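Of the tests below, the sign flips of the unadjusted counts and the higher-floor counts of whole sets were chosen beforehand, and all others only after the result was seen. Sign flips of whole lines show what the count of miRNAs would be with no treatment effect. The unflipped, real grouping is counted among the flips. For BMP4 in all lines 2 of 100 drawn flips, the real one included, gave at least the real 19 with an unadjusted p under 0.05 (highest other 22, with T-47D alone flipped). In the cancer lines 2 of 64, the real one included, gave at least the real 16 unadjusted (highest other 19, again with T-47D flipped). The cancer lines are part of all lines, so this is no separate support. For the adjusted counts of 0 in all lines (highest other 1) and 0 in the cancer lines (highest other 1) the flips say nothing, since no flip can give fewer. A technical difference that runs the same way in most lines could give such an excess too. The unadjusted counts thus argue against chance in the main setting, the only one flipped, and do not tell BMP4 from such a difference.

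In scaled signal the RNA-quality list was lower in the BMP4 arrays, by a mean of −0.31 ± 0.12 over the lines (two-sided exact sign-flip p = 0.0156, 256 flips). A response shared by the lines would give this, and so could a difference in RNA or labelling between the arrays. Brightness was tested as an explanation: with the log2 scale factor as a covariate the mean was −0.20 ± 0.10 (95% interval −0.44 to 0.04). Camera with its preset correlation still called the list lower with this covariate (adjusted p = 2.56e-05), and the miR-23/27/24 clusters higher (mean 0.30, adjusted p = 0.0247), while without the covariate both calls were lost with an estimated correlation (adjusted p = 0.278 for each); with the covariate this was not run. Since the interval over lines reaches 0, a contribution of brightness stays open. In 8 of 8 lines the BMP4 array lay in an even row of the slide and the vehicle array in an odd row, so an effect of the row may also contribute and cannot be separated here.

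In BT-474, 25 miRNAs responded differently from the other lines, 24 of them higher. With the higher floor 23 of 24 stayed more than 2 SE above the other lines, but that floor also narrows the SE (median 0.29, from 0.34) and so decides nothing by itself. The 12 that lay above background and the higher floor on both arrays were chosen so that neither floor sets their BT-474 values. Of these, 12 of 12 stayed above the other lines by more than 2 times the larger of the 2 SE. The median difference was 1.55 with either floor, as the choice largely fixed, so this count is no further support. For the rest, of which 8 of 12 stayed so, values at the floor stay open. A brightness difference alone would raise the same miRNAs in other lines that have one. When MDA-MB-361 and MCF-10A were left out of the comparison, 27 miRNAs were called higher in BT-474 (24 of them among the 24), where they averaged 1.76 ± 0.09. They averaged 0.09 ± 0.12 in MDA-MB-361, which has a larger brightness difference, and 0.07 ± 0.04 in MCF-10A, which has a similar one. Here ± is the SE over the 27 miRNAs of a single pair of arrays, which are not independent replicates. The BT-474 mean is also raised by choosing miRNAs high in that line. Within these limits, the absence of such a rise in both held-out lines argues against brightness alone. A difference in labelling or RNA quality between its arrays could contribute: the RNA-quality list averaged −0.90 in BT-474 against −0.23 (SD 0.25) in the other lines. These are scaled values, and the scale factor of BT-474 was higher on its BMP4 array by log2 0.90. A response to BMP4 particular to BT-474 remains a hypothesis, which replicate cultures of that line would test.

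In MDA-MB-361, 15 miRNAs responded differently, 14 of them lower. Signal that does not follow the RNA input and is scaled up on the dim vehicle array would leave the differences before scaling near 0. Their median was 0.59 (SD 1.18), but 6 rose by 1.33 to 1.59 and the rest lay between −2.36 and 0.60, so the median decides nothing and this explanation stays open. With the higher floor 13 of 14 stayed below the other lines, but the median SE fell to 0.16 from 0.36. The 3 that lay above background and the higher floor on both arrays were likewise chosen so that neither floor sets their values in this line. That 3 of 3 stayed below by more than 2 times the larger SE was thus largely fixed by the choice and is no further support. For the rest values at the floor stay open. The part was first defined by background alone, read from the brightest probe (9 of 9 kept in MDA-MB-361, the same 12 in BT-474). By any probe 10 of the 14 in MDA-MB-361 lay above background on both arrays. The part was narrowed after the 9 of 9 was seen, since values near the floor exclude nothing. Relative to the median of all tested miRNAs in this line the 14 lay at −1.84, and at −1.46 without scaling, −1.54 with quantile normalization and −0.25 with normexp. With 1 array per treatment, a response of these miRNAs to BMP4 and a difference between the 2 arrays cannot be told apart.

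The following values lay apart from those of the other lines. Of 32 groups of values, 7 had such a value, where about 1 in 20 (1.6 of 32) would have one in independent, unselected groups. Most groups here were miRNAs chosen for a small p in the same data, and the cancer lines are part of all lines. miR-23a-3p in BT-474 is thus counted in both, and the 1.6 is no chance level for this set. In BT-474 the BMP4 minus vehicle difference was 2.25 for miR-141-3p, 2.29 for miR-23a-3p, 2.11 for miR-27b-3p and 2.70 for miR-16-5p, against next highest values of 1.03, 0.75, 0.71 and 0.78. For miR-141-3p and miR-16-5p, not above background on the vehicle array, these are bounds of at least 4.17-fold and 5.71-fold. In MDA-MB-361 that of miR-149-5p was −1.19 (next −0.41). Among the cancer lines alone, BT-474 lay apart for miR-23a-3p (2.29) and miR-513a-5p (−1.77, next −0.90).

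The miRNAs whose response differed from the other lines with the smallest p were miR-106b-5p (1.83), let-7g-5p (2.53), miR-16-5p (2.52), miR-30b-5p (2.0) and miR-200b-3p (1.92) in BT-474, and miR-1825 (−3.14), miR-425-3p (−2.85), miR-940 (−2.68), miR-1234-3p (−2.82) and miR-1238-3p (−2.44) in MDA-MB-361.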

How the results depend on the processing

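The slide tests for lists and single lines, the fits without BT-474 and MDA-MB-361 or with brightness as covariate, the responses with line medians removed, the F test and the summed probe signals were chosen only after the results were seen. Several settings moved all tested miRNAs together: the median BMP4 difference of all tested miRNAs was −0.04 in the main setting, 0.63 with the 75th percentile over all probes, 0.38 without scaling, 0.19 in the value table, −0.13 with the gene totals and −0.21 with normexp, and the median of MCF-10A against the cancer lines −0.21, 0.27, 0.99, 0.21, −0.18 and −0.69. Signs near 0 therefore turn with the setting as a whole: of the values below that turned against 0, only 3 of 24 in all lines, 3 of 8 in the cancer lines and 1 of 13 for MCF-10A also turned relative to the median of all. The gene totals carry the preceding entry for some miRNAs; none of the reversals under those totals recurred with summed probes. Without the line as block 0 miRNAs were called for BMP4 in all lines (3 unadjusted) and 0 in the cancer lines (4 unadjusted). The cause of each turn below was not tested. By construction, the offset of normexp draws dim miRNAs together, and the percentile over all probes divides by signals about as large as the background noise.

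For BMP4 in all lines, normexp turned miR-29c-3p (−0.18), miR-29b-3p (−0.10), miR-29a-3p (−0.13), miR-141-3p (−0.05), miR-21-3p (−0.21), miR-27b-3p (−0.03) and miR-16-5p (−0.06). The 75th percentile over all probes called 44 and turned miR-575 (0.45), miR-1915-3p (0.34), miR-638 (0.35), miR-1225-5p (0.39), miR-149-5p (0.43), miR-1275 (0.35) and let-7b-3p (0.28); without scaling miR-575 was at 0.16, miR-1915-3p 0.05, miR-638 0.07, miR-1225-5p 0.10, miR-149-5p 0.15 and miR-1275 0.07. The gene totals turned miR-29a-3p (−0.14), miR-16-5p (−0.41) and miR-1275 (0.03), and the value table let-7b-3p (0.18). Of the other values of the named miRNAs 493 kept their call and sign and 10 also passed the test, against 24 turned. In the cancer lines normexp turned miR-29c-3p (−0.20), miR-21-3p (−0.16) and miR-29a-3p (−0.20), the percentile over all probes miR-1225-5p (0.24), miR-574-5p (0.18), miR-638 (0.25) and miR-1915-3p (0.24), and the gene totals miR-29a-3p (−0.24). Array weights called 1, and leaving out each line in turn called 0 to 1; 225 values stayed, 2 passed and 8 turned.

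For MCF-10A against the cancer lines, normexp turned miR-34a-5p (−0.25), miR-1288 (−0.61), miR-29b-3p (−0.22) and miR-1181 (−0.56). No scaling turned miR-25-3p (0.09), miR-33b-3p (0.03), miR-574-5p (0.11), miR-1280 (0.16), miR-92b-3p (0.05), miR-1260a (0.36), miR-1281 (0.22) and miR-93-5p (0.35), and the gene totals miR-92b-3p (0.38); 375 values stayed and 13 turned. Without a filter 11 were called, on floor values of zero variance. Single lines lost their calls with quantile normalization, with the slide as block and within their own slide: MDA-MB-231 had 0 and T-47D 0 in each, and MDA-MB-361 gained 1 within its slide. The F test called 51 within slide 1.

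For the response of MCF-10A, 13 were called without a filter, 3 with the higher floor and 2 with summed probes. For BT-474, 0 were called with normexp, 0 with the percentile over all probes and 0 without scaling, although the 24 higher miRNAs kept median responses of 2.35 and 2.82 in the last 2 (0.18 with normexp, 1.89 in the main setting); there were 45 without a filter, 7 among miRNAs above background on all arrays, 2 in the value table, and 19 to 38 when leaving out each line in turn; the gene totals turned let-7g-5p (−0.06) and miR-200b-3p (−4.03), with 92 values unchanged and 31 short of the test. With line medians removed 30 were called in the main setting and with the percentile over all probes, 31 without scaling and 1 with normexp. The split into higher and lower was 24 and 21 without a filter, 10 and 12 with the gene totals, 15 and 22 with summed probes, 25 and 6 with the mean over probes, 24 and 5 with the higher floor and 2 and 0 in the value table. For MDA-MB-361, 47 were called with normexp, 30 without scaling (miR-1238-3p at 0.07), 149 without a filter, 2 among miRNAs above background on all arrays, 24 with the higher floor, 4 with summed probes, 4 with the slide as block, and 7 to 34 when leaving out each line; 100 values of its named miRNAs stayed, 25 fell short of the test and 1 turned. With line medians removed 12 were called in the main setting, 11 with the percentile over all probes, 22 without scaling and 1 with normexp; so were 1 in HCC1954 with normexp and 2 in T-47D in the value table. Its splits were 10 and 2 in the value table, 5 and 15 with the gene totals, 2 and 2 with summed probes, 4 and 145 without a filter and 4 and 20 with the higher floor. Without a filter HCC1954 had 32, MCF-7 12, MDA-MB-231 30, MDA-MB-436 42 and T-47D 41; the higher floor gave MCF-7 7, MDA-MB-231 3 and T-47D 1, the gene totals MDA-MB-231 1 and MDA-MB-436 1, and the value table T-47D 2.

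Counts of at least 2-fold differences within a line, which carry no test, became with normexp 3 in BT-474 and 0 in MCF-10A, MDA-MB-231 and MDA-MB-436. With the gene totals they were 49 in BT-474, 6 in HCC1954, 6 in MCF-10A, 3 in MCF-7, 4 in MDA-MB-231, 5 in MDA-MB-436 and 1 in T-47D, and with summed probes 56 in BT-474, 7 in HCC1954, 0 in MDA-MB-231 and 2 in MDA-MB-436. With quantile normalization they were 2 in HCC1954, 1 in MCF-10A, 1 in MDA-MB-231, 2 in MDA-MB-436 and 4 in T-47D, and without scaling 20 in HCC1954, 33 in MCF-10A, 59 in MDA-MB-361, 6 in MDA-MB-436 and 2 in T-47D.

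The mean correlation of responses was 0.073 with quantile normalization, 0.00467 with normexp, 0.0361 without BT-474 and MDA-MB-361, and 0.0532 to 0.178 when leaving out each line. For the lists, the adjusted p with an estimated correlation was 0.278 for miR-23/27/24 and for the RNA-quality list, and in fry 0.277 and 0.132. For miR-23/27/24 it was 0.0517 with quantile normalization, 0.0619 without BT-474 and MDA-MB-361, and 0.000417 to 0.0129 when leaving out each line; for the quality list 0.0609 within slide 2 and 8.73e-06 to 0.0011 when leaving out each line. For let-7 it was 0.0262 within slide 1 and 0.265, with the sign turned, within slide 2, and 0.0387 to 0.983 when leaving out each line; without BT-474 its mean was −0.07 and without T-47D −0.01 while camera still gave the direction as higher. For miR-17/92 it was 0.0101 within slide 1, and 0.302, with the sign turned, within slide 2. It was 0.0348 with the slide as block, which drops the pairing, and 0.0387 to 0.292 when leaving out each line. In MCF-10A let-7 had an adjusted p of 0.125 with an estimated correlation, 0.428 in fry, 0.125 with quantile normalization and 0.0579 within the slide; under quantile normalization the quality list (mean 0.05, median −0.15) and miR-17/92 (mean 0.05, median −0.05) were lower in camera although their means were above 0.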

Other observations

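The miRNAs named here were chosen after their values were seen, as was the F test across the lines. miR-375, which in the breast is tied to estrogen receptor signalling, was above background on both arrays of MDA-MB-361 (log2 −0.50), BT-474 (−2.40) and T-47D (−3.23) and on both arrays of no other line (F test adjusted p = 1.78e-07). miR-31-5p, often silenced in metastatic breast cancer, was above background on both arrays of HCC1954 (−1.82) and MCF-10A (−2.76) alone. miR-100-5p was measured on both arrays of MDA-MB-231 (−0.33) and MCF-10A (−2.36), and miR-125b-5p on those of MDA-MB-231 (0.33), MCF-10A (−0.23), MDA-MB-436 (−1.84) and BT-474 (−2.09). miR-193b-3p ranged from −3.47 in MDA-MB-231 to 1.1 in MDA-MB-361. miR-29a-3p was highest in MDA-MB-231 (0.68), then MDA-MB-436 (0.02), MCF-10A (−0.20) and HCC1954 (−1.08).

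Of the 136 tested miRNAs, 65 were above background on both arrays of at least 1 line and on neither array of at least 1 other, and 42 were so on both arrays of all lines, where a miRNA counts by any of its probes (39 by its brightest probe alone). A further 6 untested miRNAs were seen in 1 line only: miR-886-3p as named in release 15 (at least 8.41-fold above the other lines), miR-138-5p (at least 2.6-fold) and miR-29b-1-5p (at least 1.44-fold) in MDA-MB-231, miR-196b-5p of a HOX cluster in T-47D (at least 2.31-fold), miR-197-3p in MDA-MB-361 (at least 2.25-fold, but 1.1-fold by its BMP4 array alone, at log2 −4.14 against −2.08 on the dim vehicle array) and miR-296-5p in MCF-7 (at least 1.28-fold).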
